A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

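Budding yeast of strain BY4741 was grown in rich medium (YPD) at 30 °C and crosslinked with formaldehyde, and chromatin was digested with micrococcal nuclease, an enzyme that cuts linker DNA and leaves the DNA wrapped around nucleosomes, per the labels' protocols. Mononucleosomal DNA was cut from a gel and made into sequencing libraries without PCR. The 14 samples carried wild-type SNF2 (WT, 3 samples) or 1 of 4 mutations of SNF2, the gene of the ATPase subunit of the SWI/SNF chromatin remodeller. These were a strain labelled dAT (3 samples), a strain labelled dSnAC (3 samples), a catalytically dead mutant with the substitution K798A (CD, 3 samples) and a SNF2 deletion (dSnf2, 2 samples).

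The files analysed here were lists of nucleosome calls that the authors made on merged replicates, 1 list per strain, per the labels. The WT and CD lists merged replicates 1, 2 and 3, the dAT list replicates 2 and 3, the dSnAC list replicates 1 and 3, and the dSnf2 list replicates 1 and 2. No list cited replicate 1 of dAT or replicate 2 of dSnAC in its label. The submitters' processing notes name Bowtie, a read aligner, and the yeast genome build sacCer3. The nucleosome caller, its smoothing and its filters are not given in the sources used here. Each call has a start, a stop, a dyad (the centre of the nucleosome), the SD of the dyad positions and an occupancy, per the file headers. The deposited occupancy is a coverage signal that sums to nearly the same total in each file, and how it was scaled is not given in the sources used here. The deposited column of conditional position, a fraction between 0 and 1, and the SD of the call length (1 column) were not used here. Other deposited values, the positions and their SDs, are in bp.

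All occupancies in a file were whole multiples of the smallest one, within a tolerance of 0.01 (100% of calls), so each was taken as a number of reads, with the smallest step as 1 read. On that reading the calls held 64981328 reads in WT, 39312292 in dAT, 31881933 in dSnAC, 59767406 in CD and 41240133 in dSnf2. The median call held 1030, 637, 514, 957 and 659 reads in the same order. Its exact 95% Poisson interval had a half-width of 6.16%, 7.85%, 8.75%, 6.39% and 7.71% of the value. Such intervals cover counting error only. With 1 pooled file per strain no count model could be fitted, no test between strains was possible, and no p-value is given. Differences are therefore described by their size, and no comparison between strains has a replicate check.

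Genes were taken from a RefSeq table of assembly R64, the assembly that sacCer3 names, with 6002 nuclear protein-coding genes. The table has no strand, so the strand was read from the W or C of the systematic name and was checked by the nucleosome depletion upstream of start codons. It holds no transcription start sites, so positions are relative to the start codon. In all, 131 genes whose start codon lies in the outer 10 kb of a chromosome were left out, and 5871 remained. Occupancies were divided by the median of the file's calls on the 16 chromosomes, outside the ribosomal DNA repeat (chromosome XII, 451000 to 469000). An occupancy of 1 is thus that of the median call. Calls were drawn as 147 bp footprints around their dyads. Promoter occupancy was the mean per base from -300 to -1 bp of the start codon, compared as log2((mutant + 0.1) / (WT + 0.1)), which understates changes at promoters of low occupancy. Genes at or above 1, or at or below -1, were counted. The nucleosome-depleted region was the widest distance between neighbouring dyads with its midpoint from -350 to 50 bp of the start codon, found separately in each strain, and the dyad on its gene side was called +1. Dyads of 2 strains were matched as mutual nearest neighbours within 73 bp, and a shift of 20 bp or more was counted. Intervals of medians are 95% order-statistic intervals over genes and describe the spread of genes, not of replicates.

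The median promoter log2 ratio of each of 13 gene lists was placed among 10000 random lists of the same size and the same deciles of WT promoter occupancy. The percentile describes these pooled files only. Of 30 ribosome biogenesis genes 29 were matched, since SIK1 is an older name of a listed gene. Genes named in the text were SNF2 and 4 auxotrophic marker genes, 5 genes studied with SWI/SNF (SUC2, PHO5, PHO8, HO, INO1), the 8 highest and 8 lowest promoter ratios per mutant among genes with a standard name and an average of WT and mutant promoter occupancy of at least 0.25, and up to 4 members of each list with the largest ratios. Groups, lists, naming rule, measures and 13 alternative settings were fixed before the data were examined. The alternatives changed the scaling, pseudocount, promoter window, call filter, footprint, gene set, size rule, match distance, gap position and shift size. For the 132 genes named by the rule in any mutant, counting error alone gave a median 95% half-width of 0.13 and a maximum of 0.94 on the log2 scale, computed on reads without the pseudocount. In simulated data drawn around the WT calls at the depth of dAT, with 5871 genes, 197 of 200 promoters raised 4-fold and 198 of 200 lowered to 0.25 of WT passed the size rule of 1, as did 0 of 5322 untouched promoters. A 30 bp shift of +1 was recovered in 199 of 200 genes. The changed genes were drawn only from those of higher WT promoter occupancy, and the noise was counting error alone. The simulation therefore does not show recovery at promoters of low occupancy or of smaller changes at single genes. It also does not show how often 2 real files differ without a cause. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.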

Results

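Nucleosome positions and occupancies were measured by MNase-seq in wild-type yeast and in 4 mutants of SNF2, the catalytic subunit of SWI/SNF, a remodeller that uses ATP to slide and evict nucleosomes. The mutants addressed how parts of the protein contribute: the AT-hook region and the SnAC domain, which the names dAT and dSnAC are read here as lacking, the ATPase, inactivated in CD by K798A, and the whole protein, absent in dSnf2. Each strain had 1 pooled list of calls, with 63281 nuclear calls in WT, 63289 in dAT, 63263 in dSnAC, 63471 in CD and 63272 in dSnf2. The lists rest on 31881933 (dSnAC) to 64981328 (WT) reads. There are no replicate values, so every difference below is between pooled files.

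SNF2 itself (YOR290C, chromosome XV, 855147 to 860258, minus strand, sacCer3) was examined first as a check of the labels. Mean occupancy over the open reading frame was 0.663 in WT, 0.796 in dAT, 0.731 in dSnAC and 0.732 in CD, where 1 is the median call. In dSnf2 it was 0.00559, or 0.844% of WT, with 124 reads in place of 23730. A stretch without a call of at least 0.25 spanned the whole 5112 bp of the gene in dSnf2. In dSnAC the widest such stretch was 528 bp (855909 to 856436, codons 1275 to 1450), and in dAT it was 233 bp (855704 to 855936, codons 1441 to 1519). In WT and CD it was 148 bp and 137 bp, and a point substitution such as K798A leaves no gap to see. Each of 4 marker genes had the same state in all 5 strains: MET17 (methionine synthesis) had 0 calls, URA3 (uracil synthesis) held at most 8 reads, and the middle one of 5 equal parts of HIS3 (histidine synthesis) was at 0. LEU2, a leucine synthesis gene, was covered in all 5 strains at 0.994 to 1.16.

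**Figure D1:**
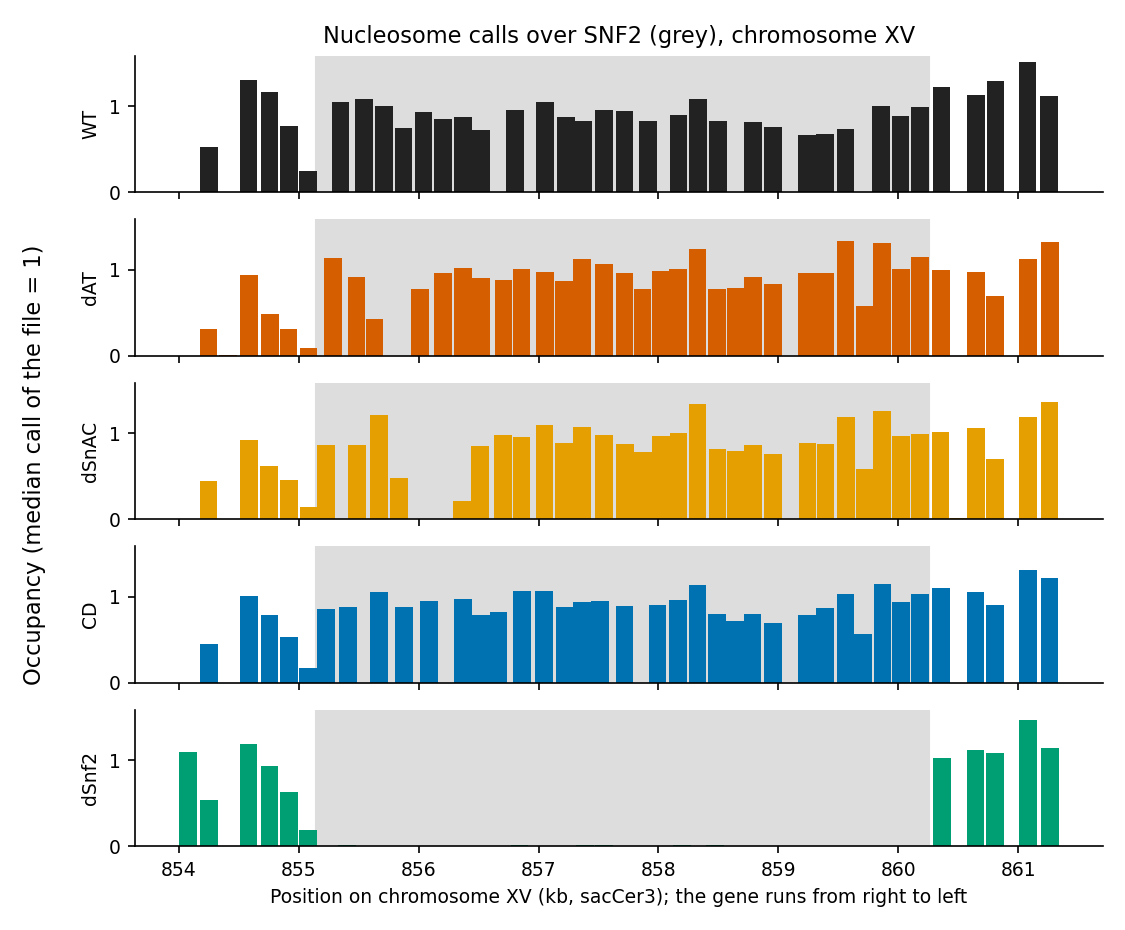
Nucleosome calls over SNF2 and 1000 bp on each side in the 5 pooled files; bars are 147 bp wide at the dyad (horizontal axis, position on chromosome XV in kb), their height is the occupancy with the median call of the file as 1, and grey marks the open reading frame. In dSnf2 the 28 calls within the frame hold 124 reads and are too low to see, and a stretch without a call of at least 0.25 measures 528 bp in dSnAC and 233 bp in dAT.

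Across the genome, nucleosomes lay at nearly the same places in all 5 strains. Between 96.5% (dAT) and 97.0% (CD) of WT dyads had a partner within 73 bp in a mutant, and the median displacement was 2 or 3 bp. At the spacing given below, 73 bp on each side takes in most positions, and the share for unrelated positions was not computed. The displacement is therefore the more telling value. Displacements of 20 bp or more concerned 9.19% of matched dyads in dAT, 8.67% in dSnAC, 8.84% in CD and 9.01% in dSnf2. By the same measure the pairs of mutants had 5.53% for dAT and dSnAC, 4.92% for CD and dSnf2, and 7.21% to 8.62% for the other pairs. The share of matched dyads did not separate mutants from WT, with 96.7% between dAT and dSnf2. The SD of the promoter log2 ratio over genes was 0.10 between dAT and dSnAC and 0.10 between CD and dSnf2. It was 0.15 between dAT and CD, 0.20 between dAT and dSnf2, 0.12 between dSnAC and CD and 0.16 between dSnAC and dSnf2. Between WT and dAT, dSnAC, CD and dSnf2 it was 0.24, 0.20, 0.17 and 0.14. The median dyad SD, a measure of how loosely a nucleosome is placed, was 29.5 to 30.0 bp, and neighbouring dyads lay a median of 167 or 168 bp apart.

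The median architecture of promoters was also close to WT in every mutant, while single genes differed in both directions. The median nucleosome-depleted region was 241 bp in WT, dAT and CD and 242 bp in dSnAC and dSnf2, and the median difference per gene was 1, 1, 0 and -1 bp in dAT, dSnAC, CD and dSnf2. The region was wider by 20 bp or more in 531, 472, 374 and 375 genes and narrower by as much in 489, 440, 385 and 346. These counts include genes in which the widest gap was at another place than in WT. They therefore do not show that the same gap widened or narrowed. The +1 nucleosome had its median dyad at -13 bp of the start codon in all strains. It lay 20 bp or more downstream of its WT place in 74 genes of dAT, 65 of dSnAC, 48 of CD and 48 of dSnf2, and upstream in 108, 101, 99 and 120 genes. In 1087, 1000, 885 and 805 genes, of 5745, 5742, 5744 and 5742 measured, the widest gap itself was at another place. Within genes, +1 and +2 lay 167 bp apart in WT and dSnf2, 166 bp in CD and 165 bp in dAT and dSnAC.

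The occupancy of promoters was lower than in WT in all 4 mutants, most in dAT and least in dSnf2. The median promoter had 0.767 in WT, 0.603 in dAT, 0.639 in dSnAC, 0.684 in CD and 0.723 in dSnf2. The median log2 ratio was -0.30 in dAT, -0.23 in dSnAC, -0.15 in CD and -0.085 in dSnf2, and promoters were lower in 90.0%, 89.1%, 87.1% and 80.4% of the 5871 genes. The 95% intervals of these medians over genes were -0.302 to -0.288, -0.235 to -0.223, -0.153 to -0.145 and -0.088 to -0.082. The median was below 0 on 16 of 16 chromosomes in each mutant. Occupancy was also lower downstream of stop codons: the mean from 101 to 200 bp past the stop was 0.681 in WT, 0.500 in dAT, 0.541 in dSnAC, 0.588 in CD and 0.633 in dSnf2. The lowest point of the mean profile, at -138 bp, was 0.470 in WT and 0.358, 0.384, 0.415 and 0.443 in the mutants in the same order. The first 1000 bp of genes over the promoter gave a ratio of 1.12 in WT, 1.43 in dAT, 1.35 in dSnAC, 1.26 in CD and 1.19 in dSnf2.

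**Figure D2:**
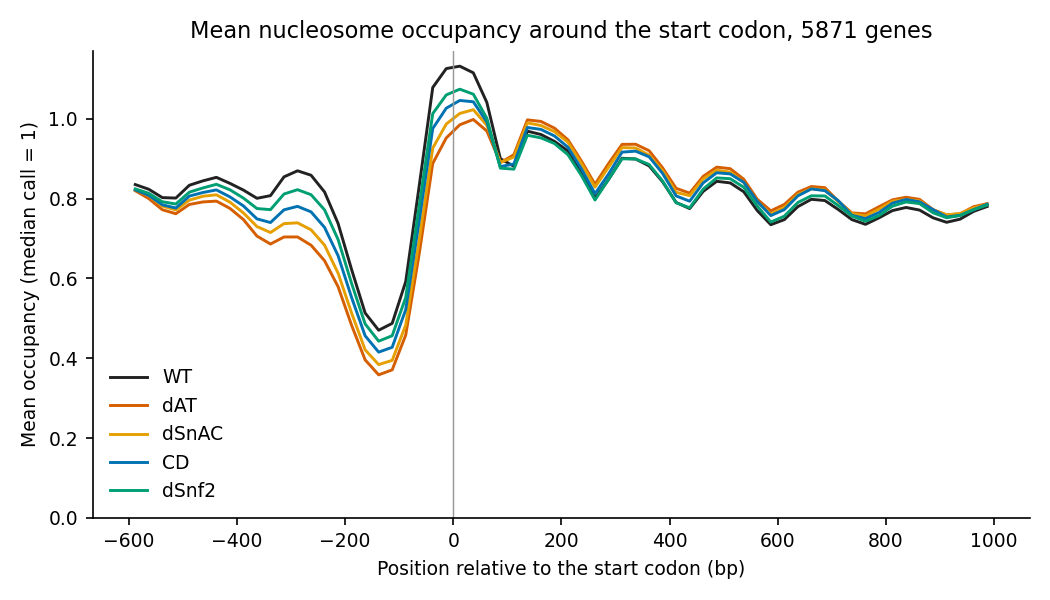
Mean occupancy (vertical axis, median call of each file as 1) in 25 bp windows around the start codon (horizontal axis, bp) over 5871 genes, 1 line per pooled file. At -138 bp the lines order from WT (0.470) through dSnf2 (0.443), CD (0.415) and dSnAC (0.384) to dAT (0.358).

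**Figure D3:**
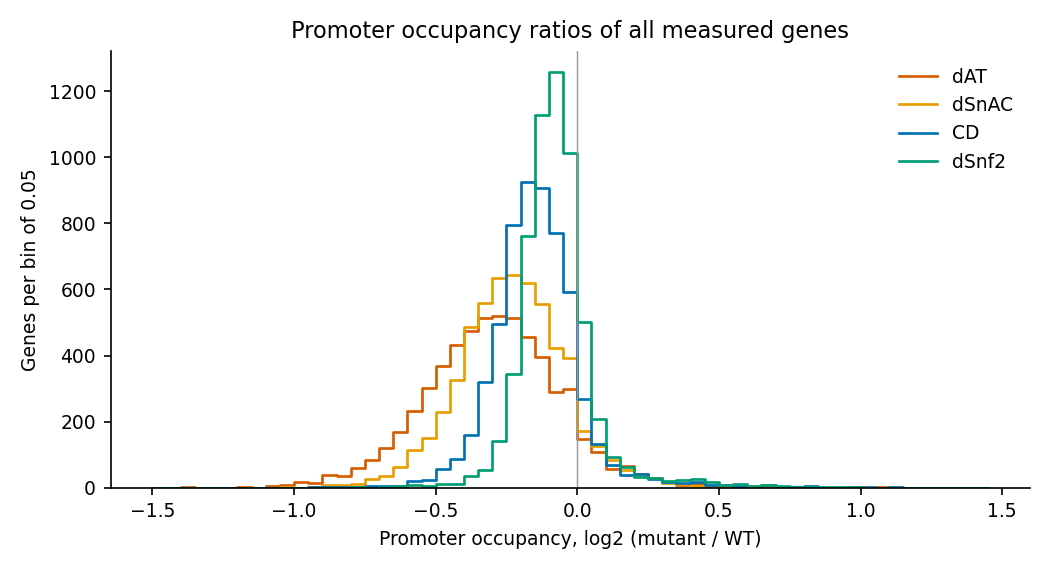
Number of genes (vertical axis) per bin of 0.05 of the promoter log2 ratio of mutant to WT (horizontal axis), 1 line per mutant. The medians lie at -0.30 in dAT, -0.23 in dSnAC, -0.15 in CD and -0.085 in dSnf2.

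In dAT, with all calls kept, ribosomal protein promoters were low relative to all genes. Those of the iron regulon were high relative to all genes, with a median near that of WT. RPL37A and RPL31A, which encode proteins of the large ribosomal subunit, had log2 ratios of -1.28 and -1.09, and 38 of 132 ribosomal protein genes were at or below -0.58. SIS1, an Hsp40 co-chaperone, had -1.25 (0.731 in WT, 0.251 in dAT), PFK1, a subunit of phosphofructokinase, -1.09, and ARG3, the ornithine carbamoyltransferase of arginine synthesis, -1.35 from a low WT occupancy of 0.177. FLC2 had -1.17, DCV1 -1.15, HSM3, a proteasome assembly chaperone, -1.08 and UBA3, part of the Rub1-activating enzyme, -1.05. On the higher side stood MTC7 with 1.09, YAT1, a carnitine acetyltransferase, with 0.72, CLB1, a B-type cyclin, with 0.61, MMO1 with 0.61, GAL3, the galactose sensor, with 0.61, TIR1, a cell wall mannoprotein, with 0.59, ECL1 with 0.55 and OPT1, an oligopeptide transporter, with 0.52. By the size rule 2 genes were higher (MTC7 and the unnamed frame YBR219C, 1.05, chosen after its value was seen) and 23 were lower. With a pseudocount of 0.25 there were 0 and 0, without calls below 0.25 there were 3 and 49, and with the window of -200 to -1 bp 5 and 52. At a rule of 0.58 the counts were 12 and 646. Relative to the median gene, a setting added after the data were seen, they were 6 and 3 at a rule of 1 and 79 and 66 at 0.58.

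As groups, the iron regulon stood 0.29 above the all-gene median in dAT, at percentile 100 after rounding, with 8 of 17 members above WT. SIT1, a siderophore transporter, had 0.31 and FRE2, a ferric reductase, 0.47, while FET3, the multicopper oxidase of iron uptake, had -0.98 and SMF3, a vacuolar metal transporter, -0.54. Loci used as models of SWI/SNF action stood 0.16 above the all-gene median (percentile 99.9), which with the shorter window of -200 to -1 bp was 0.04 and inside the random lists. Ribosomal proteins stood at -0.11 (percentile 0). Without calls below 0.25 the value was 0.01, so its sign against all genes rests on weak calls. With all calls, the matched random lists spanned -0.027 to 0.095, so a value near 0 is not by itself a reversal against them. With the filter 1 list still lay below the random lists in dAT. The percentile of ribosomal proteins with the filter is not given here. The other 10 lists lay inside the central 95% of random lists, among them glycolysis at 0.14 (percentile 91.8, and -0.01 without calls below 0.25) and heat shock genes at -0.08 (percentile 6.16), where SIS1, BTN2 (-0.86), STI1 (-0.66) and HSP78 (-0.64) were lowest.

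In dSnAC, 6 of the 8 highest and 3 of the 8 lowest named genes were those of dAT. Ratios of both mutants share the WT file, so this recurrence is not independent. RPS1B, a small-subunit ribosomal protein, had -1.03, PFK1 -1.02, SIS1 -0.94, the mitotic cyclin CLB2 -0.92, ZUO1, a ribosome-associated Hsp40, -0.90, the ammonium permease MEP3 -0.89, the lysine permease LYP1 -0.88 and FLC2 -0.87. MTC7 was highest with 0.99, followed by YAT1 (0.68), YHB1, a flavohemoglobin that removes nitric oxide (0.67), MMO1 (0.67), SUR7, an eisosome protein (0.65), TIR1 (0.64), OPT1 (0.61) and CLB1 (0.61). The size rule counted 1 gene as higher, YBR219C with 1.05, chosen after its value was seen, and 7 as lower. With a pseudocount of 0.25 there were 0 and 0, without calls below 0.25 there were 2 and 20, and with the window of -200 to -1 bp 6 and 15. At 0.58 the counts were 18 and 221, and relative to the median gene they were 4 and 1 at a rule of 1 and 50 and 28 at 0.58.

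Glycolysis, the iron regulon and the SWI/SNF model loci stood above the random lists in dSnAC, at 0.26, 0.24 and 0.14 relative to all genes (percentiles of 100 after rounding). Among glycolytic genes TDH3, the main glyceraldehyde-3-phosphate dehydrogenase, had 0.42, while PGK1 (phosphoglycerate kinase) had -0.59 and FBA1 (aldolase) -0.35. With the window of -200 to -1 bp glycolysis was at 0.03, inside the random lists, and the model loci were at -0.03. In the iron regulon ENB1, an enterobactin transporter, had 0.49, FRE2 0.51 and FET3 -0.84. Ribosomal proteins were at -0.13 (percentile 0), with 28 of 132 at or below -0.58, and at 0.03 without calls below 0.25. The other 9 lists lay inside the central 95%.

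In CD, promoters of 10 of 16 glycolytic genes and 12 of 17 iron regulon genes had more nucleosome occupancy than in WT, and the median promoter was nearer to WT than in dAT and dSnAC. IES6, a subunit of the INO80 remodeller, had 1.14, but -0.07 with the window of -200 to -1 bp, so its higher occupancy lay upstream of -200 bp. MTC7 had 0.92, YHB1 0.85, ZEO1 0.84, TDH3 0.84 (0.26 in WT, 0.54 in CD), the glucose transporter HXT3 0.81, RPS22B, a small-subunit ribosomal protein, 0.80 and OPT1 0.78. The lowest were LSM5, of the Lsm ring that binds RNA ends, at -0.92, HXT11, a hexose transporter, at -0.88, the alcohol dehydrogenase ADH4 at -0.85, RPS25B at -0.81, PFK1 at -0.79, the telomere protein RIF2 at -0.76, WTM1 at -0.74 and MET6, the methionine synthase, at -0.71. HXT11 has a near-identical relative, HXT9, and reads may be divided between them by the alignment, so its value is uncertain. The size rule counted 4 genes as higher, IES6, HXT9 (1.02 from a WT occupancy of 0), YPL062W (1.03) and YJR146W (1.11), of which the last 3 were chosen after their values were seen, and 0 as lower. With a pseudocount of 0.25 there were 0 and 0, and without calls below 0.25 there were 6 higher and 8 lower. At 0.58 there were 31 higher and 37 lower, against 60 and 12 relative to the median gene.

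Glycolysis in CD stood 0.42 above the all-gene median (percentile 100), and 0.13 with the window of -200 to -1 bp. TDH3, GPM1 (phosphoglycerate mutase, 0.69) and ADH1 (alcohol dehydrogenase, 0.53) were highest and PFK1 lowest. The iron regulon stood at 0.25 (percentile 100), with 12 of 17 members above WT, led by ENB1 (0.56), FRE2 (0.49), SIT1 (0.42) and the siderophore transporter ARN1 (0.39). Ribosomal proteins stood at -0.06 (percentile 0), where the random lists spanned -0.0056 to 0.071. The value against all genes turned to 0.01 with the window of -200 to -1 bp and to 0.07 without calls below 0.25. Mating genes were at 0.08 (percentile 96.0) and the SWI/SNF model loci at 0.05 (percentile 96.3), both inside the central 95% with the 8 remaining lists.

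In dSnf2, which lacks the protein, the general reduction was smallest and 5 of the 8 highest and 3 of the 8 lowest named genes were those of CD. Here too the shared WT file can bring the same genes to the ends. ZEO1 had 1.20, IES6 1.11 (0.12 with the window of -200 to -1 bp), HXT3 1.05 (0.37 in WT, 0.88 in dSnf2), TDH3 0.92, the ADP/ATP carrier AAC1 0.91, the amino acid permease BAP2 0.85, OPT1 0.81 and GYP8, a GTPase activator of vesicle transport, 0.80. SIR2, the silencing deacetylase (chromosome IV, 376757 to 378445, minus strand), was lowest with -1.13, from 0.797 to 0.309, and was at -0.36, -0.27 and -0.22 in dAT, dSnAC and CD. MET6 followed with -0.80, HXT11 with -0.79, the translation-associated TMA10 with -0.76, SPO24 with -0.72, LYP1 with -0.68, MET13, a methylenetetrahydrofolate reductase, with -0.65 and RIF2 with -0.65. The size rule counted ZEO1, IES6 and HXT3 as higher and SIR2 as lower. With a pseudocount of 0.25 there were 0 and 0, and without calls below 0.25 there were 7 and 6. At 0.58 there were 42 higher and 18 lower. Relative to the median gene the counts were 6 and 1 at a rule of 1 and 56 and 7 at 0.58.

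The glycolytic list in dSnf2 stood 0.44 above the all-gene median (percentile 100), and 0.25 with the window of -200 to -1 bp, with 12 of 16 members above WT and 4 at or above 0.58: TDH3, GPM1 (0.72), ENO2 (enolase, 0.70) and ADH1 (0.65). The iron regulon stood at 0.23 (percentile 100), led by ENB1 (0.54), ARN1 (0.45), SIT1 (0.41) and FRE2 (0.38). Mating genes stood at 0.10 (percentile 99.8), with 11 of 20 members above WT, among them SST2, a regulator of pheromone signalling (0.52), STE4, the beta subunit of the pheromone-coupled G protein (0.42), and STE2, the alpha-factor receptor (0.40). Genes of amino acid synthesis under the activator Gcn4 were at -0.04 (percentile 1.21), with ARG3 at -0.58 and HIS5 at 0.40. With a pseudocount of 0.25, and with either other promoter window, they lay inside the random lists. Ribosomal proteins were at 0.02, at the lower edge of the random lists (0.015 to 0.078, percentile 2.69). The SWI/SNF model loci were at 0.01 (percentile 78.5), and 9 of 13 lists lay inside the central 95%.

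**Figure D4:**
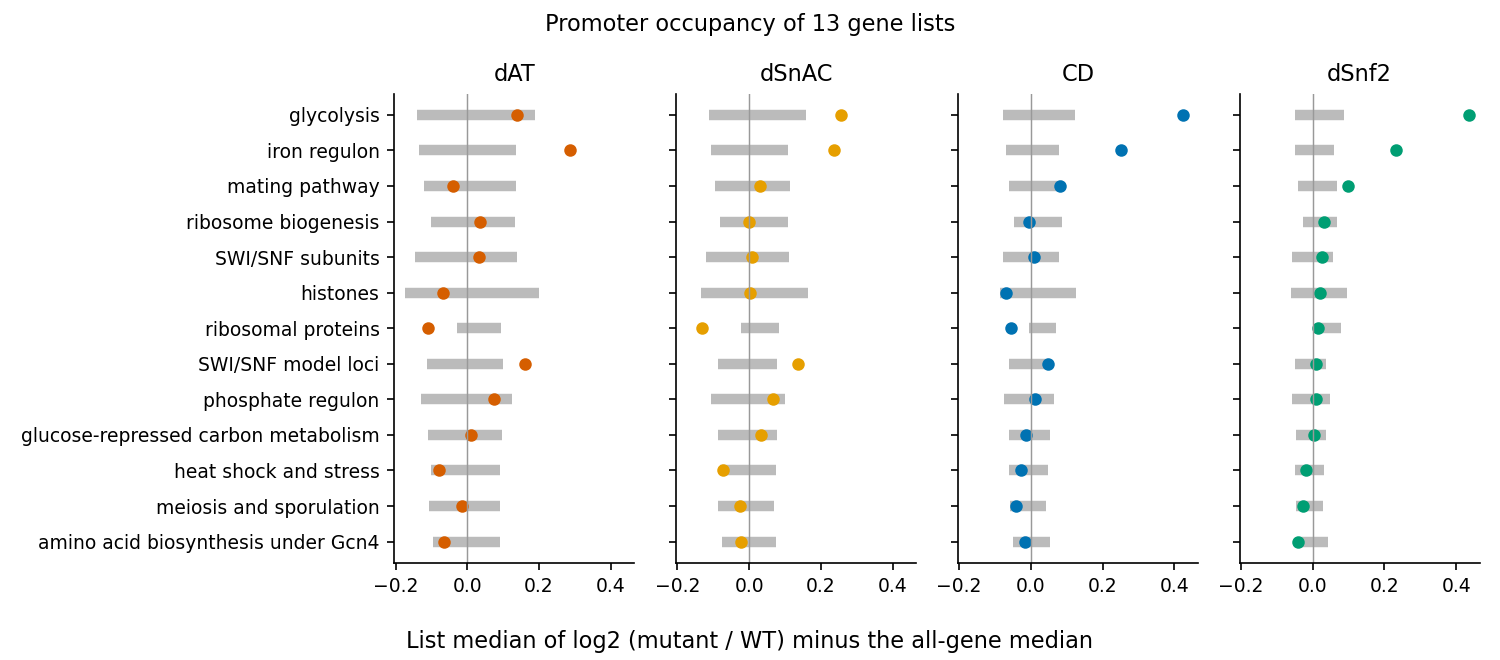
Median promoter log2 ratio of 13 gene lists relative to the all-gene median (horizontal axis), 1 panel per mutant and 1 row per list; points are the lists and grey bars span the central 95% of 10000 random lists matched on WT occupancy. The iron regulon lies between 0.23 and 0.29 in the 4 mutants, and glycolysis goes from 0.14 in dAT to 0.44 in dSnf2.

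Genes long studied with SWI/SNF showed small ratios. SUC2, the invertase gene, had -0.56 in dAT, -0.41 in dSnAC, -0.33 in CD and -0.23 in dSnf2, each below the all-gene median. PHO5, an acid phosphatase of the phosphate response, had 0.04, 0.11, 0.23 and 0.25, each above it by 0.33 to 0.38. PHO8, the vacuolar alkaline phosphatase, had -0.09, -0.11, -0.16 and -0.07. The mating-type endonuclease gene HO had -0.27, -0.31, -0.14 and -0.14, and INO1, of inositol synthesis, -0.17, -0.06, -0.10 and -0.05.

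Promoters past a size rule of 0.58 were shared between mutants. Of 646 lower promoters in dAT, 221 in dSnAC, 37 in CD and 18 in dSnf2, 204 were shared by dAT and dSnAC, with 24.3 for independent lists. The other pairs, with that number in brackets, shared 30 in dAT and CD (4.07), 23 in dSnAC and CD (1.39), 12 in dAT and dSnf2 (1.98), 12 in CD and dSnf2 (0.113) and 8 in dSnAC and dSnf2 (0.678). Of 12, 18, 31 and 42 higher promoters, 27 were shared by CD and dSnf2 (0.222), 14 by dSnAC and CD (0.0950), 14 by dSnAC and dSnf2 (0.129), 9 by dAT and dSnAC (0.0368), 8 by dAT and dSnf2 (0.0858) and 7 by dAT and CD (0.0634). Simulated unchanged mutants against the same WT file shared 0 promoters by Poisson counting. In them 0 genes passed the rule of 0.58 in any mutant, so this result was fixed in advance and is no baseline. When the simulated files differed as CD and dSnf2 do, they shared 1.25 lower in dAT and dSnAC and 1.17 higher in CD and dSnf2. CD and dSnf2 had the smallest promoter SD of all pairs of strains, so this spread is the mildest choice. The WT file cannot be split, so part of the excess may come from it. Neither simulation holds the general fall of all promoters, which by itself raises the number of shared lower promoters. Relative to the median gene, a setting added after the data were seen, 20 promoters were lower in both dAT (66) and dSnAC (28), with 0.315 for independent lists, and 43 higher in both CD (60) and dSnf2 (56), with 0.572. At the rule of 1 the overlaps were 5 lower in dAT and dSnAC and 1 higher in CD and dSnf2.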

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

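The tests of explanations in this part were chosen after the results were seen, while the gene lists and their matched random lists were fixed before. Calls on the mitochondrial chromosome, which no comparison used, held 0.0462% of the occupancy in dSnf2 and 0.0371% in WT, a share above the control. The other mutants lay below WT, at 0.00424% in dAT, 0.00884% in dSnAC and 0.0328% in CD.

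Promoter occupancy was lower in all 4 mutants, most in dAT. Depth as the cause is argued against by dAT and dSnf2, which held 39312292 and 41240133 reads and yet differed by a median of 0.22 (log2) over genes. The extent of MNase digestion had what it needs: between convergent genes, where no promoter lies, the median log2 ratio in dAT was -0.45 over 1276 regions, 1.52 times that of promoters. It therefore remains a candidate explanation. The files with the largest fall, dAT and dSnAC, also held the lowest mitochondrial shares and were near each other in promoter ratios (SD 0.10), so another difference in their preparation stays open too. The deletion of SNF2 was nearest to WT, 0.21 above dAT, but with 1 file per strain this does not exclude loss of SWI/SNF activity as the cause. An effect of losing the AT-hook or SnAC region, as the strain names are read here, on AT-rich linkers is open and untested, since no genome sequence was used here.

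Glycolytic promoters were above the random lists in dSnAC, CD and dSnf2, most in CD and dSnf2. In dAT they lay inside the random lists (0.14 relative to all genes, percentile 91.8). Reads shared between paralogs were examined in 6 members picked as lacking a close paralog. Their median in dSnf2 was 0.49 relative to all genes, with 5 of 6 above the all-gene median. The highest, GPM1 (0.80) and CDC19 (0.58), do have paralogs. The rest were at 0.53 (PGI1), 0.46 (TPI1), 0.18 (FBA1) and -0.13 (PGK1). Shared reads are thus argued against for PGI1 and TPI1, and stay open for the list. Compared directly, dSnf2 over dAT, the list was 0.27 above all genes (central 95% of random lists up to 0.20). WT drops out of this comparison by arithmetic, so the value is no test of a deviation of the WT file. It stays open for the rise that mutants share. Digestion stays open as well: the list was 0.30 higher in dSnf2 than in dAT, but 1 file per strain gives no spread for this difference. No biological explanation was tested, and the list was also 0.26 above all genes in dSnAC.

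The iron regulon was higher than all genes in all 4 mutants. Low WT occupancy of the chosen promoters stays open: the list lay above the random lists matched on it, yet the 7 members at or above the all-gene median of WT occupancy were at 0.22, 0.14, 0.12 and 0.0054 in dAT, dSnAC, CD and dSnf2. A deviation of the WT file alone, for example in its growth or iron supply, had what it needs in the list medians, which differed between mutants by at most 0.055. Single members differed more, such as FET3 with -0.98 in dAT and 0.04 in dSnf2, and over open reading frames the list went from 0.20 in dAT to 0.077 in dSnf2. Its open reading frames were above the random lists too, except in CD. An effect common to all 4 SNF2 mutations would give the same picture and stays open.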

How the results depend on the processing

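Relative to the median gene, at size rules of 1 and of 0.58, was the only setting chosen after the data were seen. No paired analysis was possible because the replicates of a strain were merged in 1 file, and no replicate could be left out. The median promoter ratio was below 0 in 40 of 40 values, the median difference in width of the nucleosome-depleted region stayed within its interval in 12 of 12 and occupancy over SNF2 within 0.05 in 5 of 5. The 40 values include the size rule of 0.58, which cannot change a median. They also include the footprint from start to stop, which repeated the main values. Of 827 values for 47 named genes, the sign differed from the main one in 5 for dAT, 4 for dSnAC, 3 for CD and 3 for dSnf2. Apart from the 5 genes studied with SWI/SNF, these genes were picked as the extremes of the main setting. Stable signs were thus largely given by their selection. The values include the setting relative to the median gene. The list medians over 9 settings were 0.23 to 0.33 for the iron regulon in dAT and 0.25 to 0.58 for glycolysis in dSnf2, 0.13 to 0.50 in CD, 0.028 to 0.37 in dSnAC and -0.012 to 0.28 in dAT. Counts at the size rule of 1 are small, and some of them moved with most settings. The cause was not tested, except where fewer or more genes or calls pass by construction. The median call held 514 to 1030 reads, and counting error alone gave named genes a half-width of up to 0.94 on the log2 scale (ARG3 in dAT, 11 reads). The error between replicates is not known.

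Median promoter log2 ratios in dAT, dSnAC, CD and dSnf2 were -0.27, -0.21, -0.13 and -0.075 with scaling by the mean occupancy, and -0.27, -0.21, -0.14 and -0.074 with scaling by the total occupancy. They were -0.25, -0.19, -0.13 and -0.072 with a pseudocount of 0.25. With the window of -200 to -1 bp they were -0.27, -0.21, -0.14 and -0.080, and with -400 to -51 bp -0.28, -0.21, -0.14 and -0.078. With calls of at least 0.25 of the median they were -0.29, -0.22, -0.14 and -0.081. With windows overlapping no other gene dAT, dSnAC and CD had -0.32, -0.25 and -0.16.

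Scaling by the mean gave 3 genes higher in dSnAC, and scaling by the total 2 higher and 4 lower. With a pseudocount of 0.25 there were 0 genes higher and 0 lower in dAT, dSnAC, CD and dSnf2, and 0 lists below the random lists in dSnf2. The window of -200 to -1 bp gave 5, 6, 13 and 11 genes higher and 52, 15, 8 and 2 lower in dAT, dSnAC, CD and dSnf2, with 1 list above in dAT and 1 in dSnAC, and 3, 2 and 2 below in dAT, dSnAC and CD. There the model loci turned to -0.026 in dSnAC, ribosomal proteins to 0.013 in CD and IES6 to -0.072 in CD. The window of -400 to -51 bp gave 46, 24 and 1 genes lower in dAT, dSnAC and CD and 5 higher in dSnf2, with 4 lists above in CD and 5 in dSnf2. Genes in the outer 10 kb gave 2 lists below in dSnf2, and windows overlapping no other gene gave 0 genes higher in dAT and 0 in dSnAC. Relative to the median gene there were 6, 4 and 6 genes higher in dAT, dSnAC and dSnf2 and 3 and 1 lower in dAT and dSnAC. Higher in both were 3 (dAT and dSnAC), 2 (dAT and CD), 1 (dAT and dSnf2), 2 (dSnAC and CD), 1 (dSnAC and dSnf2) and 3 (CD and dSnf2), and lower in both 1 (dAT and dSnAC). Relative to the median gene with a size rule of 0.58 there were 79, 50, 60 and 56 genes higher and 66, 28, 12 and 7 lower in dAT, dSnAC, CD and dSnf2. Higher in both were 35, 31, 26, 37, 34 and 43, and lower in both 20, 6, 1, 5, 1 and 2, in the same order of pairs.

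With calls of at least 0.25 of the median there were 49, 20, 8 and 6 genes lower in dAT, dSnAC, CD and dSnf2, and 2 and 7 higher in dSnAC and dSnf2. Ribosomal proteins turned to 0.013, 0.028 and 0.066 in dAT, dSnAC and CD. Higher in both were 2 (dAT and dSnAC), 4 (CD and dSnf2) and 1 in each other pair, and lower in both 17 (dAT and dSnAC), 7 (dAT and CD), 5 (dAT and dSnf2), 7 (dSnAC and CD), 5 (dSnAC and dSnf2) and 5 (CD and dSnf2). The distance from +1 to +2 was 168 bp in WT and 166 bp in dAT, and 96.2% of WT dyads were matched in dAT.

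At the size rule of 0.58 there were 12, 18, 31 and 42 genes higher and 646, 221, 37 and 18 lower in dAT, dSnAC, CD and dSnf2. Higher in both were 9 (dAT and dSnAC), 7 (dAT and CD), 8 (dAT and dSnf2), 14 (dSnAC and CD), 14 (dSnAC and dSnf2) and 27 (CD and dSnf2), and lower in both 204, 30, 12, 23, 8 and 12 in the same order. A match distance of 40 bp left 93.0%, 93.4%, 93.4% and 93.1% of WT dyads matched. A shift of 10 bp or more counted 253, 210, 134 and 123 genes downstream and 234, 229, 204 and 216 upstream.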

Other observations

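Over whole open reading frames, a measure looked at only after the promoter results were seen, several gene lists lay outside the random lists matched on WT occupancy of the frame. Ribosome biogenesis genes, which are highly transcribed in growing cells, were above all genes by 0.18 in dSnAC, 0.14 in CD and 0.13 in dSnf2, each above the random lists, and by 0.19 in dAT, inside the random lists (percentile 93.4). Meiosis and sporulation genes, which are silent in rich medium, were at -0.19, -0.17, -0.10 and -0.069 in dAT, dSnAC, CD and dSnf2, with percentiles of at most 0.75. The iron regulon was above all genes over frames as well as promoters, by 0.20 in dAT, 0.14 in dSnAC and 0.077 in dSnf2 (percentiles 99.6, 98.1 and 98.6), and by 0.091 in CD, inside the random lists (percentile 95.6).

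Heat shock genes were at 0.12 in dAT and 0.070 in CD (percentiles 99.8 and 99.7). They lay inside the random lists in dSnAC (0.072, percentile 97.3) and dSnf2 (-0.0092, percentile 26.0). Glycolysis was at 0.23 in dSnAC (percentile 99.3) and inside the random lists in dAT (0.22), CD (0.14) and dSnf2 (0.11). Genes under Gcn4 were at 0.070 in dSnAC (percentile 99.3), the phosphate regulon at 0.032 in dSnf2 (percentile 97.8) and ribosomal proteins at -0.0099 in dAT (percentile 1.50). Each of these lists lay inside the random lists in the other mutants.

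Regions between genes differed by the direction of their neighbours. In dAT the median log2 ratio was -0.45 between convergent genes (1276 regions), -0.36 between tandem genes (2578) and -0.25 between divergent genes (1353), and in dSnf2 the values were -0.11, -0.09 and -0.08. LEU2 was covered by calls in all 5 strains although the background BY4741 is known to carry a deletion of it.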
